A study of Mus musculus with 12 samples.

How the data were processed

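The study measured RNA in conventional dendritic cells (cDCs) sorted from the spleens of mice. According to the labels' protocols, RNA was isolated with a column kit for small samples, copied to cDNA with a SMART-Seq HT kit and made into sequencing libraries with a Nextera XT kit. These kits do not mark the strand of the RNA. Sample titles give 4 groups of 3 libraries each, L-cDC1, M-cDC1, L-cDC2 and M-cDC2, numbered 1 to 3 in each group.

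The deposited table holds FPKM values, which are read counts scaled by gene length and library total, as the name of the deposited table and its gene length column show. The submitters' processing notes name Trim Galore 0.6.7, Trimmomatic 0.39, cutadapt 3.7, STAR 2.7.9a, featureCounts 2.0.1 and DESeq2 1.20.0, without the role or order of each. They also name the human build GRCh38, whereas the gene symbols in the deposited table are those of the mouse. The table itself names no build. Of 21777 protein-coding symbols, 21168 were found in the GENCODE M21 annotation of mouse build GRCm38, and 643 of these (3.04%) had a start within 100 bp of it. Coordinates are therefore given as the deposited table gives them, with the build not given in the sources used here. The table has 55322 rows, of which 1705 carry a symbol that occurs more than once, and each such row was kept apart. It lists 0 genes of chromosome M, so the fixed list of mitochondrially encoded genes had no member to test.

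Each FPKM value multiplied by the gene length was a whole multiple of the worth of 1 read in that library, within 0.01 read, for 100% of values in each library. Recovered totals ran from 15879864 to 24498235 reads per library. On a gene of 1 kb, 3 reads were worth 0.122 FPKM in the deepest library and 0.189 FPKM in the shallowest. PCR duplicates could not be removed, so this floor covers counting error only.

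Genes with at least 1 FPKM in at least 3 of the 12 libraries were tested, which left 12434. Values were transformed as log2(FPKM + 1) without rescaling. A linear model with 1 mean per group was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3, with an intensity trend and 8 residual degrees of freedom. The contrasts were L minus M within each subset, cDC1 minus cDC2 within M and within L, and the interaction, which is the L minus M difference in cDC1 minus that in cDC2. P-values from limma were adjusted by the Benjamini-Hochberg method over the genes tested in each contrast, and a gene was called at an adjusted p under 0.05. A log2 difference is on the log2(FPKM + 1) scale, which understates the change of genes at low levels. Where a group is at or near 0 the difference depends on the pseudocount and is not a bound. Levels are given as mean ± SD of 3 libraries, and the error of a log2 difference is its standard error (SE).

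The sample grouping, the contrasts, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where an alternative is said to have been added. Of 30 gene lists fixed, 29 had tested members. They cover cDC1 identity, cDC2 identity, the cDC2A and cDC2B classes, genes of lymphoid progenitors, plasmacytoid DCs (pDCs), monocytes and macrophages, B cells, plasma cells, T and NK cells, neutrophils, erythroid cells and platelets, stromal and endothelial cells, DC maturation, MHC class II and class I presentation, the type I interferon response, the cell cycle, the immediate early and dissociation response, trafficking receptors and integrins, cytokines and chemokines, innate sensors, DC transcription factors, haematopoietic growth factor receptors, immune checkpoints and costimulation, glycolysis, cytosolic ribosomal proteins, oxidative phosphorylation and sex-linked genes. Some genes stand in several lists, for example Csf1r and Lyz2. Lists were tested with camera in limma at a preset correlation of 0.01 between genes, with an estimated correlation beside it, and p-values were adjusted over the 29 lists of a contrast. The limma test fry was also fixed in advance and run. It asks whether list members change at all, not whether they differ from other genes. Only its results for L minus M in cDC1 are given here.

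Named genes were chosen by rule. For each L minus M contrast these were the 10 largest rises and 10 largest falls among called genes whose groups did not overlap and whose higher group had a mean of at least 5 FPKM, leaving out immunoglobulin and T cell receptor segments and unnamed gene models. To these were added up to 4 members with the smallest p from each list, any called marker of another cell type, and Xcr1, Clec9a, Irf8, Batf3, Sirpa, Irf4, Il7r, Rag1, Flt3 and Zbtb46. For the cDC1 minus cDC2 contrasts the rule took 5 genes in each direction and the identity lists, and for the interaction the 6 genes with the smallest p. All named genes that passed the interaction test are given with the results that differ between subsets. Called list members given as examples in the cDC1 minus cDC2 contrasts, and members named because 5 or fewer passed in a direction, were chosen after their values were seen where the rule does not name them. Some genes that the rule names are not reported here.

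The alternatives fixed in advance were a pseudocount of 0.1, no filter, a filter of 5 FPKM, median-of-ratios scaling, quantile normalization, the sample number as a replicate block, a fit to the compared groups alone, limma without the trend, and each library left out in turn. Added after seeing the data were limma-voom on the recovered reads, a correction for gene length and GC content, and a fit without lymphocyte list genes. That fit left out immunoglobulin and T cell receptor genes and the B cell, plasma cell and T and NK cell lists. Other genes of lymphocytes, such as Fcmr, Ly6d and Cd2, stayed in it. The statistical steps were tested on simulated data with known changes, made from the mean of each gene over all 12 libraries. The spread between libraries was assumed, not estimated from these data, and genes were drawn independently. The shares recovered below hold for that assumed spread only. Genes changed 4-fold were recovered at 92.8% for L minus M in cDC1 and 90.7% in cDC2, 96.9% and 94.8% for cDC1 minus cDC2 in M and L, and 78.6% for the interaction. For 2-fold changes these shares were 46.3%, 43.8%, 54.6%, 45.4% and 5.05%. Of the unchanged genes, 10 of 11644 were called for L minus M in cDC1 and 14 of 11658 in cDC2. For cDC1 minus cDC2 this was 14 of 11626 in M and 12 of 11650 in L, and for the interaction 8 of 11628. For L minus M in cDC1, 44 and 90 genes with 2-fold and 4-fold changes were recovered beside the 10 false calls. Between 11820 and 11851 genes were run in each. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.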

Results

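The study set cDCs of lymphoid origin, as its title names the subject, beside other cDCs of the mouse spleen. The sample titles carry the letters L and M without spelling them out, and they are used here as given. A cDC is a cell that takes up antigen and presents it to T cells, and the subsets cDC1 and cDC2 depend on different transcription factors. The labels give the genotype Il7r-cre with a Rosa26 tdTomato reporter, while the design text speaks of wild type C57BL/6J mice of 7 to 8 weeks. In such a reporter mouse, cells with a history of Il7r expression become fluorescent, and lymphocytes share that history. The labels do not say which libraries were sorted on the reporter. RNA of each of 12 samples was sequenced, 3 in each of L-cDC1, M-cDC1, L-cDC2 and M-cDC2, to a depth of 15879864 reads in M-cDC2 replicate 2 up to 24498235 reads in M-cDC2 replicate 1. The labels do not tie the replicates to separate animals, so p-values measure the spread between these samples, which may be technical. An exact permutation test of 3 against 3 libraries cannot go below a two-sided p of 0.1, so limma, which pools the spread over genes, was the test used throughout.

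Between 10394 and 11570 genes reached 1 FPKM in a library. Across genes, which are not independent replicates, Pearson correlations of log2 values ran from 0.958 to 0.979 within groups. They ran from 0.954 to 0.974 between L-cDC1 and M-cDC1, from 0.935 to 0.96 between L-cDC2 and M-cDC2, and from 0.82 to 0.862 between cDC1 and cDC2. No pair of replicates differed as little as counting noise alone would give, with chi-square values per gene of 22.6 to 41.5. Every library held the male-linked transcript Ddx3y, at 13.8 to 31.8 FPKM. Immunoglobulin and T cell receptor genes took 0.0903% to 0.426% of the reads in L libraries, most in L-cDC2 replicate 2, and 0.0573% to 0.0658% in M libraries.

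**Figure D1:**
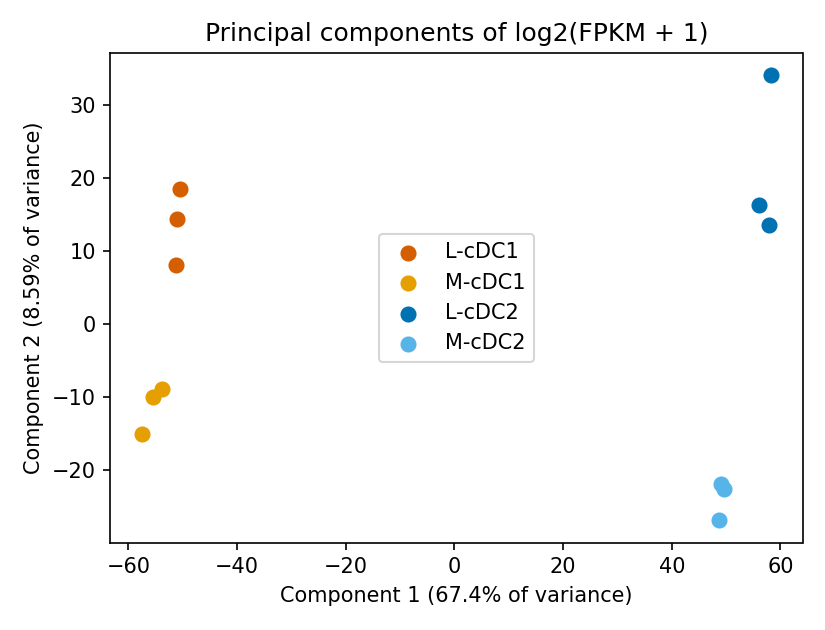
Principal components of log2(FPKM + 1) over the tested genes, with 1 point per library and the share of variance on each axis. The cDC1 libraries lie at -57.5 to -50.5 on the first axis (67.4% of variance) and the cDC2 libraries at 48.8 to 58.3, while on the next axis (8.59%) L libraries lie at 8.15 to 34.1 and M libraries at -26.9 to -8.91.

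The comparison of cDC1 with cDC2 asked how far the subsets differ within each of L and M, and it also checks the labels. Xcr1, the receptor for the chemokine Xcl1 and a marker of cDC1, stood at 206 ± 33 FPKM in L-cDC1 and 225 ± 24.3 in M-cDC1 (SD, n = 3 each), against 0.88 and 1.62 in L-cDC2 and M-cDC2. Sirpa, the Cd47 receptor that marks cDC2, stood at 184 ± 12 in L-cDC2 and 215 ± 14.5 in M-cDC2, against 0.826 and 0.365 in L-cDC1 and M-cDC1. The log2 difference cDC1 minus cDC2 of Xcr1 was 6.44 (SE 0.147, limma adjusted p = 1.96e-12) in M and 6.77 (adjusted p = 8.92e-13) in L. That of Sirpa was -7.31 in M (SE 0.191, adjusted p = 4.73e-12) and -6.71 in L.

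All 20 cDC1 identity genes were higher in cDC1, both within M and within L, and the same 20 passed when adjusted over the list alone. Their median was 4.64 in M (camera adjusted p = 3.18e-30) and 4.97 in L (2.7e-29). Among them, Cd8a differed by 6.60 in M and 7.01 in L, and Clec9a, the receptor for actin exposed by dead cells, by 5.13 and 5.78. Irf8, a transcription factor cDC1 development needs, differed by 5.42 and 5.51, and Tlr3, a sensor of double-stranded RNA, by 4.48 and 4.62. Batf3, which keeps Irf8 on in cDC1, differed less, by 0.78 in M (adjusted p = 0.000128) and 0.88 in L. Of the 20 cDC2 identity genes 18 were lower in cDC1 in each of M and L, also when adjusted over the list alone, with medians of -4.22 (adjusted p = 3.67e-15) and -3.33 (1.22e-13). They included the lectin genes Clec4a4 (-7.62 in M and -7.58 in L) and Cd209a (-5.55 and -4.86), and Irf4 (-3.73 and -2.93), a transcription factor of cDC2. The exception was Clec12a, higher in cDC1 by 2.33 in M and 3.14 in L. Notch2 did not pass in either, at -0.23 (adjusted p = 0.257) and -0.18 (0.363). Both identity lists held with an estimated correlation, at adjusted p = 0.00024 and 0.000308 in M and 0.00027 and 0.000438 in L.

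The largest differences that met the naming rule included Gpr141b (6.60 in M and 6.67 in L) and Gcsam (6.55 and 6.53) toward cDC1, and Sirpb1a (-7.46 and -7.27), Cd7 (-6.49 and -6.34) and the transglutaminase gene Tgm2 (-6.11 and -6.22) toward cDC2. Flt3, the growth factor receptor of the DC lineage, was higher in cDC1 by 0.45 in M (adjusted p = 0.00706) and 0.80 in L (8.13e-05). In M its call ended under quantile normalization (adjusted p = 0.0575, range over the alternatives 6.18e-05 to 0.0575). Il7r, a receptor of lymphoid progenitors, was lower in cDC1 by -1.43 in M and -1.68 in L, with levels of 0.162 FPKM in M-cDC1 and 2.15 in M-cDC2, 0.176 in L-cDC1 and 2.86 in L-cDC2. Zbtb46, a transcription factor shared by cDCs, did not pass, at -0.33 in M (adjusted p = 0.0745) and -0.19 in L (0.312, with its sign turned under median-of-ratios scaling).

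Among the cDC2 classes, 7 of 9 cDC2A genes fell in cDC1 relative to cDC2 in M (median -3.92, adjusted p = 6.62e-06, and 0.0357 with an estimated correlation) and 6 of 9 in L (-3.82, adjusted p = 6.6e-05, and 0.0498). The counts were unchanged when adjusted over the list alone. Esam, an adhesion molecule of cDC2A, differed by -2.89 in M and -3.20 in L. Of 9 cDC2B genes, 7 were lower and 2 higher in M (Clec12a and Ccr2), with a median of -1.5 (adjusted p = 0.018, and 0.192 with an estimated correlation). In L 6 were lower and the same 2 higher, or 3 higher adjusted over the list alone (median -1.97, adjusted p = 0.121). Ccr2 in M, at 0.47, lost its call without any M-cDC2 library and without M-cDC1 replicates 1 and 2 (adjusted p up to 0.181).

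Genes of the type I interferon response were lower in cDC1 than in cDC2. In M 24 of 32 were lower and 2 higher, also when adjusted over the list alone (median -1.52, adjusted p = 5.93e-07, and 0.0357 with an estimated correlation). In L 20 were lower and 3 higher, or 22 and 4 adjusted over the list alone (-1.53, adjusted p = 2.33e-05, and 0.0498). Named after their values were seen, Rtp4 differed by -5.58 in M and -5.28 in L, and the RNA-sensing synthetase Oas2 by -4.48 and -4.74. The exceptions were Mx1 (0.92 and 0.97), Trim30a (1.01 and 1.16) and, in L, Ifi44 (0.89). Of 18 MHC class I presentation genes, 8 were higher and 2 lower in M, B2m and H2-Q4, also adjusted over the list alone (median 0.244, adjusted p = 0.00136, and 0.121 with an estimated correlation). In L 9 were higher and B2m was lower, with the same counts over the list alone (0.377, adjusted p = 0.000392, and 0.101). Psmb9, a subunit of the immunoproteasome, differed by 1.15 in both M and L, and Pdia3, a chaperone of peptide loading, by 1.37 in M, and both genes were chosen after their values were seen. The H2-Q4 call ended without M-cDC1 replicates 1 and 2 and M-cDC2 replicates 1 and 3 (adjusted p up to 0.105). Quantile normalization ended the class I call in M (adjusted p = 0.0768, range over the alternatives 0.00136 to 0.121).

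Some genes of protein synthesis and respiration were called higher in cDC1, more of them in M than in L, but neither list passed with an estimated correlation. Of 79 cytosolic ribosomal protein genes, 58 rose and 0 fell in M, or 63 adjusted over the list alone (median 0.548, adjusted p = 1.62e-16, and 0.211 with an estimated correlation). In L 24 rose and 1 fell, Rps27 (-0.47, adjusted p = 0.0251), with the same counts over the list alone (0.236, adjusted p = 1.89e-07, and 0.375). The Rps27 call ended without L-cDC1 replicates 1 and 2 and without L-cDC2 replicates 2 and 3 (adjusted p up to 0.106). Of 76 oxidative phosphorylation genes 34 rose and 1 fell in M, Cox6b2 (adjusted p = 0.00911), or 40 and 2 adjusted over the list alone (0.34, adjusted p = 5.99e-11, and 0.132 with an estimated correlation). In L 18 rose and Cox6b2 fell (-1.05), with the same counts over the list alone (0.157, adjusted p = 6.6e-05, and 0.28). Limma-voom, added after seeing the data, ended the Cox6b2 call in M (adjusted p = 0.07, range over the alternatives 0.00137 to 0.07), as quantile normalization did (0.0634), and in L (0.0572, range 0.000935 to 0.0572). Of 15 glycolysis genes 7 rose and 3 fell in each (medians 0.223 and 0.31, adjusted p = 0.0147 and 0.00549, and 0.192 and 0.187 with an estimated correlation), or 8 rose in L adjusted over the list alone. The fallers were Hk1, Eno1 and the lactate carrier Slc16a3. The hexokinase gene Hk3 differed by 4.39 in M and 4.23 in L, and was named after its values were seen. Of 30 cell cycle genes 17 were lower in M, or 20 adjusted over the list alone (-0.478, adjusted p = 0.0208, and 0.472 with an estimated correlation), and 24 in L, or 25 (-0.816, adjusted p = 0.000104, and 0.28).

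Markers of other cell types also differed between the subsets. Of 5 erythroid and platelet markers 4 were higher in cDC1 in M, also adjusted over the list alone (median 1.8, adjusted p = 0.000913, and 0.104 with an estimated correlation), and 5 of 5 in L (2.34, adjusted p = 2.33e-05, and 0.0498). The haemoglobin gene Hba-a1 differed by 2.73 in M and 3.68 in L, and Hbb-bs by 2.44 and 3.16. Of 11 T and NK cell markers, 10 were lower in cDC1 in L, or 11 adjusted over the list alone (-1.43, adjusted p = 0.00116, and 0.211 with an estimated correlation). They included Gzma (-3.18), a granule protease of killer cells. In M the marker Klre1 alone passed, at -0.70, or none adjusted over the list alone (adjusted p = 0.859), and its call ended without M-cDC1 replicates 1 and 3 and M-cDC2 replicates 2 and 3 (adjusted p up to 0.106). Of 16 B cell markers, 10 were lower and Fcrla (2.05) higher in L, the same over the list alone (-1.44, adjusted p = 0.0315, and 0.476 with an estimated correlation), and 6 lower and 3 higher in M (adjusted p = 0.637). Cd22, an inhibitory receptor, differed by -3.59 in M and -3.18 in L. Beside these counts, 25 to 70 immunoglobulin kappa V genes had at least 3 reads in each L library and 0 to 5 in each M library. Of 7 lymphoid progenitor genes, Il7r, Cd7, Tcf7, Bcl11a and Satb1 were lower in cDC1 in M and in L (medians -1.08 and -1.07, adjusted p = 0.0043 and 0.000785, and 0.104 and 0.0498 with an estimated correlation), or 6 in L adjusted over the list alone.

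Other lists passed with the preset correlation alone or not at all. DC transcription factors had 4 higher and 21 lower of 31 in M (22 lower adjusted over the list alone, adjusted p = 0.00319, and 0.132 with an estimated correlation) and 6 higher and 18 lower in L (0.0292 and 0.216). Innate sensors had 4 higher and 15 lower of 25 in M (adjusted p = 0.0188, and 0.104 with an estimated correlation), and 4 and 13 in L (adjusted p = 0.0507). Growth factor receptors (adjusted p = 0.0218, and 0.196 with an estimated correlation) and immediate early genes (0.0462 and 0.447) passed in M but not in L (0.108 and 0.369). MHC class II presentation had 5 higher and 7 lower of 15 in M (adjusted p = 0.52) and 7 and 7 in L (0.844), and in M H2-Aa (0.23) and H2-Ab1 (0.45) turned sign under quantile normalization. In M and L respectively, adjusted p was 0.094 and 0.844 for DC maturation, 0.666 and 0.108 for cytokines, 0.457 and 0.108 for trafficking receptors, 0.132 and 0.427 for checkpoints, 0.45 and 0.108 for pDC markers, 0.0766 and 0.552 for monocyte markers, 0.266 and 0.967 for plasma cell markers, 0.52 and 0.552 for neutrophil markers, 0.266 and 0.137 for stromal markers and 0.252 and 0.0793 for sex-linked genes. Under quantile normalization the median of DC maturation in L turned from -0.168 to 0.0441, and that of cytokines in M from -0.139 to 0.0127.

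In total 4736 of 12434 genes passed in M (1573 higher and 3163 lower in cDC1) and 4913 in L (1605 and 3308). Of these, 1224 were higher in both (203 by chance if the lists were independent), 2312 were lower in both (841 by chance) and 5 passed in opposite directions. The share of higher genes depended on the scaling. It was 33.2% in M and 32.7% in L as deposited, with medians over all genes of -0.177 and -0.193, against 48.9% and 48.7% after median-of-ratios scaling (medians -0.0263 and -0.0357) and 53.4% and 52.6% after quantile normalization (medians 0.0442 and 0.0249). The ribosomal and oxidative phosphorylation medians kept their direction after quantile normalization, at 0.474 and 0.339 in M.

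The comparison of L-cDC1 with M-cDC1 asked whether cDC1 of the L and M groups differ. Of 16 B cell markers 7 were called higher in L-cDC1, and of 11 T and NK cell markers 3, while 0 of 20 cDC1 identity genes passed the test. With an estimated correlation neither lymphocyte list passed (adjusted p = 0.0944 for each). Igkc, the constant region of the immunoglobulin kappa light chain (chromosome 6, 70703419 to 70703950 in the deposited table), was at 245 ± 141 FPKM in L-cDC1 and 2.38 ± 0.876 in M-cDC1 (SD, n = 3 each), a log2 difference of 6.07 (SE 0.541, limma adjusted p = 0.000169). Ly6d, a surface protein of early B lineage cells (chromosome 15, 74633905 to 74635469), was at 28.3 ± 14.8 against 0.0251 ± 0.0434 FPKM (4.67, SE 0.42, adjusted p = 0.000169). Fcer1g, the signalling chain of Fc receptors (chromosome 1, 171057141 to 171061934), fell from 57.5 ± 6.31 FPKM in M-cDC1 to 27.6 ± 2.31 in L-cDC1 (-1.03, SE 0.112, adjusted p = 0.000676).

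Of 16 B cell markers 7 rose in L-cDC1 and 0 fell, or 12 rose adjusted over the list alone (median 1.38, camera adjusted p = 9.67e-21, and 0.0944 with an estimated correlation). Besides Igkc they included the lambda constant gene Iglc2 (4.39), Cd79a (3.76) and Cd79b (2.94), which carry the signal of the B cell receptor, Fcer2a (1.59) and the complement receptor Cr2 (1.49). Of 11 T and NK cell markers Nkg7 (2.71), a protein of cytotoxic granules, and the T cell receptor constant genes Trbc2 (1.95) and Trac (1.53) rose, or 8 adjusted over the list alone (1.05, adjusted p = 1.27e-10, and 0.0944 with an estimated correlation). Of 6 plasma cell markers Jchain, the joining chain of secreted antibodies, rose by 2.50, or 2 markers adjusted over the list alone (1.52, adjusted p = 0.00392, and 0.295 with an estimated correlation). Fcmr, the Fc receptor for IgM, also rose (2.66, adjusted p = 0.000676). In these same libraries 25, 43 and 48 kappa V genes had at least 3 reads in L-cDC1, against 1, 2 and 0 in M-cDC1.

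The cDC1 identity list did not pass, with 0 of 20 members called, also over the list alone (median -0.0282, adjusted p = 0.729). Xcr1 differed by -0.13 (adjusted p = 0.837), Clec9a by -0.18 (0.747), Irf8 by 0.070 (0.95) and Batf3 by -0.081 (0.884), and the signs of the last pair depended on the setting. Flt3 differed by 0.022 (0.98, with the sign turned under median-of-ratios scaling), Zbtb46 by 0.28 (0.523), Sirpa by 0.37 (0.547), Irf4 by 0.48 (0.493) and Il7r by 0.016 (0.998). Rag1, which cuts antigen receptor genes in lymphocyte precursors, was at 0.00264 FPKM in L-cDC1 and listed at 0 in each other group, and was too low to be tested. The cDC2 identity list had 0 of 20 called, or 1 higher and 1 lower adjusted over the list alone (adjusted p = 0.764).

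Il12b, the p40 chain of interleukins Il12 and Il23 and a member of the DC maturation and cytokine lists (chromosome 11, 44290890 to 44304860), was at 30.6 ± 6.8 FPKM in L-cDC1 and 16.1 ± 0.709 in M-cDC1 (0.87, SE 0.162, adjusted p = 0.0369). It was the called member of 21 in DC maturation, of which 7 rose adjusted over the list alone (median 0.308, adjusted p = 1.22e-06, and 0.106 with an estimated correlation), and of 21 cytokine genes, also over the list alone (adjusted p = 0.499). Ccr7, which guides DCs to lymph nodes, differed by 0.62 (adjusted p = 0.0629). Among 31 DC transcription factors Spib (1.70, adjusted p = 0.0181), active in B cells and pDCs, and Nfil3 (1.69, 0.0322), which acts upstream of cDC1 commitment, rose, also over the list alone (adjusted p = 0.00902, and 0.199 with an estimated correlation). Of 9 cDC2A genes Dtx1, a regulator of Notch signalling, rose (1.13, adjusted p = 0.008), or 3 adjusted over the list alone (0.265, adjusted p = 0.00452, and 0.139 with an estimated correlation). Yrdc (1.87), the phosphatase Dusp2 (1.80) and Nsmce4a (1.71) were among the largest rises.

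Of 79 ribosomal protein genes 0 passed over all genes tested, while 43 were lower adjusted over the list alone (median -0.342, adjusted p = 2.1e-27, and 0.169 with an estimated correlation). Rpl27 differed by -0.44 (adjusted p = 0.147). Of 76 oxidative phosphorylation genes 0 passed, or 3 adjusted over the list alone (-0.262, adjusted p = 9.28e-18, and 0.106 with an estimated correlation). No member was called of the cDC2B list (-0.307, adjusted p = 0.00378, and 0.139 with an estimated correlation, with 1 lower over the list alone), the monocyte list (-0.348, 0.00462 and 0.229, with 2 lower), the cell cycle list (-0.112, 0.00485 and 0.481), the immediate early list (0.159, 0.00638 and 0.349, with 2 higher) or the erythroid and platelet list (0.461, 0.00648 and 0.186, with 1 higher). Ly6d was the called member of 7 lymphoid progenitor genes (0.261, adjusted p = 0.00455, and 0.106 with an estimated correlation), and with Spib the pair called among 14 pDC markers (0.764). Adjusted p was 0.972 for MHC class II, MHC class I and stromal genes, 0.764 for the type I interferon response and sex-linked genes, 0.829 for neutrophil markers, 0.367 for trafficking receptors, 0.499 for innate sensors, 0.729 for growth factor receptors, 0.249 for checkpoints and 0.667 for glycolysis.

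In total 49 genes passed in this contrast, 44 higher (11 of them immunoglobulin or T cell receptor genes) and 5 lower, and 1278 had an unadjusted p under 0.05. The 5 lower genes, named after their values were seen apart from Fcer1g, were Fcer1g, Krt80 (-0.97), BC147527 (-0.62), Gm35853 (-1.30) and the short segment Ighj1, whose call rests on 0 reads in each L-cDC1 library against 7, 1 and 6 reads in M-cDC1. The count moved to 83 without L-cDC1 replicate 1, 102 without M-cDC1 replicate 1, 24 without M-cDC1 replicate 2 and 26 without M-cDC1 replicate 3, and 11 of 25 named calls ended in 1 or more of these fits. Without M-cDC1 replicate 2 the adjusted p was 0.177 for Il12b, Nfil3, Dusp2 and Yrdc, 0.103 for Spib, 0.231 for Nsmce4a, 0.0711 for Trbc2, 0.13 for Krt80 and BC147527 and 0.081 for Gm35853, and without M-cDC1 replicate 3 it was 0.0592 for Ighj1; L-cDC1 replicates 2 and 3 ended 9 and 8 of the named calls. Of the 25, Fcer1g, Fcmr and Ly6d were the 3 kept under every alternative that tested them. Of the others, 19 calls ended without a filter, 15 with the compared groups alone and 12 with limma-voom. Limma-voom put Igkc at an adjusted p of 0.207 (range over the alternatives 3.13e-05 to 0.207) and Cd79a at 0.138 (0.000281 to 0.138).

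The comparison of L-cDC2 with M-cDC2 asked the same of cDC2. Genes of lymphocytes were higher in L-cDC2, and genes shared by monocytes and the cDC2B class were lower. Igkc was at 990 ± 884 FPKM in L-cDC2 and 2.14 ± 0.0805 in M-cDC2 (SD, n = 3 each), a log2 difference of 7.86 (SE 0.541, limma adjusted p = 6.19e-06). Lyz2, the lysozyme of myeloid cells (chromosome 10, 117113236 to 117118226 in the deposited table), fell from 932 ± 113 FPKM in M-cDC2 to 252 ± 88.2 in L-cDC2 (-1.93, SE 0.179, adjusted p = 5e-05). Csf1r, the receptor for macrophage colony-stimulating factor (chromosome 18, 61233670 to 61265221), fell from 65.3 ± 2.16 to 24.1 ± 3.26 FPKM (-1.41, SE 0.148, adjusted p = 0.000107).

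**Figure D2:**
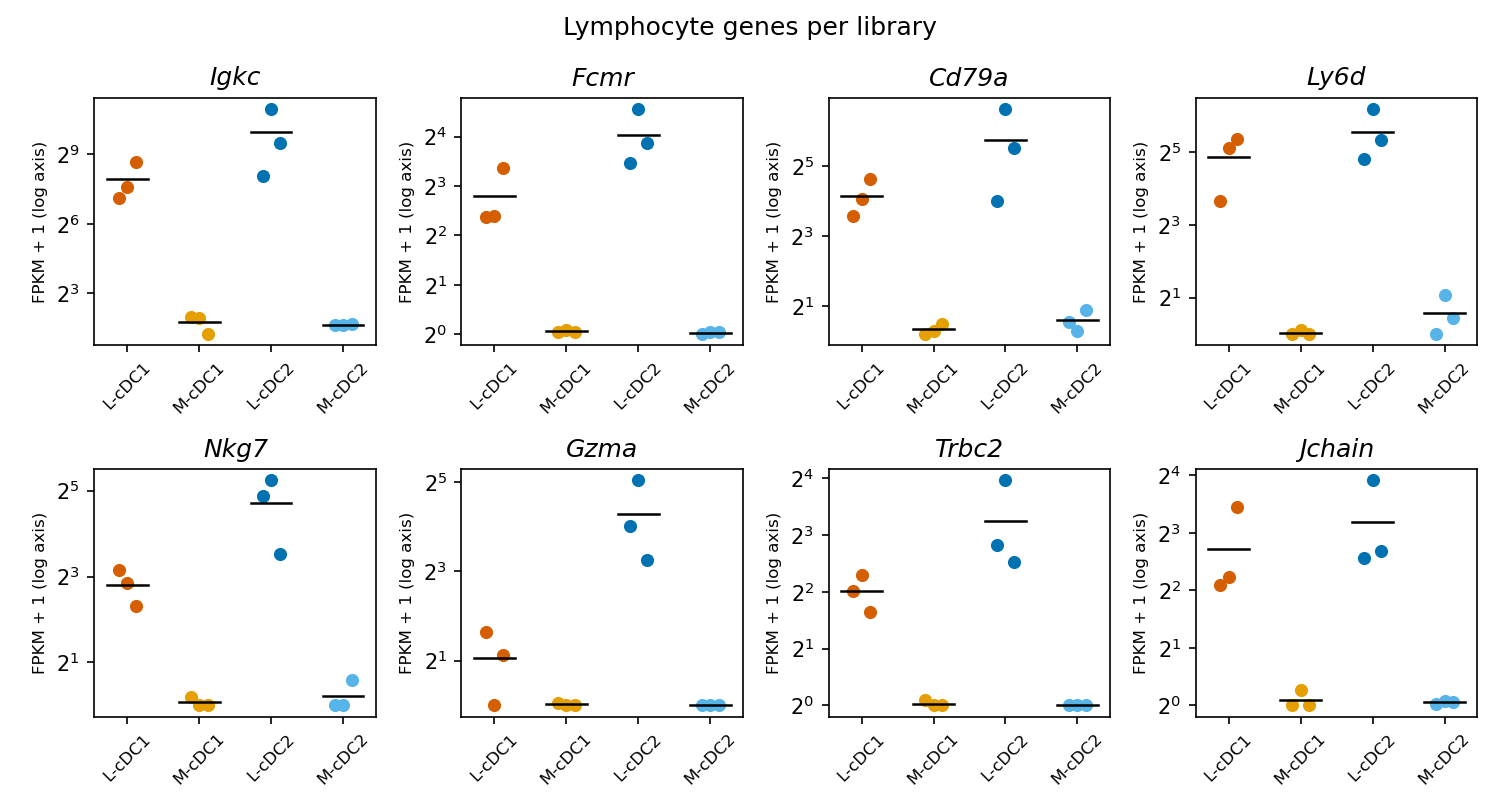
FPKM + 1 on a log axis for 8 genes of lymphocytes in each library, with points for libraries and bars for means of 3. Igkc, for example, has means of 245 FPKM in L-cDC1 and 990 in L-cDC2, against 2.38 in M-cDC1 and 2.14 in M-cDC2.

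Of 11 T and NK cell markers 9 rose in L-cDC2, or 11 adjusted over the list alone (median 2.35, camera adjusted p = 4.45e-27, and 0.00504 with an estimated correlation). Nkg7 differed by 4.35, with 25.2 ± 13.4 FPKM in L-cDC2, the granule protease Gzma by 4.10, with 18.5 ± 11.9 FPKM against 0 in each M-cDC2 library, the NK receptor Ncr1 by 2.60 and perforin, Prf1, by 2.19. Of 16 B cell markers 10 rose, or 14 adjusted over the list alone (1.65, adjusted p = 4.45e-27, and 0.0163 with an estimated correlation), among them Iglc2 (6.08) and Cd79a (4.81). Of 6 plasma cell markers Jchain (3.01) and Iglv1 (4.94) rose, or 3 adjusted over the list alone (2.21, adjusted p = 7.94e-06, and 0.0883 with an estimated correlation). Of 18 lymphoid progenitor genes only 7 were high enough to be tested. Among the 7, Ly6d (4.94), the T cell factor Tcf7 (1.36) and the pre-B cell gene Vpreb3 (1.87) rose, also over the list alone (0.258, adjusted p = 5.62e-05, and 0.0183 with an estimated correlation). Il7r, of the same list, did not pass. Other rises by the naming rule were Fcmr (3.93), the T and NK cell adhesion molecule Cd2 (3.51), and Gimap4 (3.81) and Gimap3 (3.57), GTPases of lymphocytes. S1pr1 (2.49), a receptor of lymphocyte recirculation, and 1 other gene rose while Ccr2 and Cx3cr1 fell among 22 trafficking genes, or 4 and 5 adjusted over the list alone (adjusted p = 0.137). In these libraries 47, 70 and 65 kappa V genes had at least 3 reads in L-cDC2, against 2, 1 and 5 in M-cDC2.

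Of 18 monocyte and macrophage markers Lyz2, Csf1r, Ccr2 (-1.55), Ace (-1.98) and Ear2 (-1.05) fell and Apoe (1.05), a lipid carrier of macrophages, rose, or 10 fell and 2 rose adjusted over the list alone (median -0.839, adjusted p = 1.58e-12, and 0.0141 with an estimated correlation). Of 9 cDC2B genes 6 fell and 1 rose, or 6 and 2 adjusted over the list alone (-1.12, adjusted p = 1.94e-06, and 0.019 with an estimated correlation). The fallers were Lyz2, Csf1r, Ccr2, Clec12a (-1.12), Cd209a (-1.03) and Cx3cr1 (-1.37). Cd209a stood at 171 ± 14.4 FPKM in L-cDC2 and 351 ± 35.1 in M-cDC2. Of 20 cDC2 identity genes 5 fell, Cd209a, Clec12a, Csf1r, Tmem176a (-0.96) and Tmem176b (-0.57), or 7 fell and 1 rose adjusted over the list alone (-0.273, adjusted p = 0.000109, and 0.0141 with an estimated correlation). Sirpa (-0.22, adjusted p = 0.779) and Irf4 (-0.33, 0.701) did not pass, nor did Irf8, Batf3 (-0.18, 0.67), Zbtb46 (0.13, 0.821), Flt3 (-0.33, 0.265), Il7r (0.26, 0.809) and Xcr1 (-0.47, 0.186). The largest falls by the naming rule were Adgre4 (-2.23, adjusted p = 0.000196), an adhesion receptor of monocytes and macrophages, Cd300lb (-1.94), the lectin receptor Clec7a (-1.88), the chemokine Ccl9 (-1.84), Wfdc17 (-1.75), Clec4a3 (-1.67) and Depdc7 (-1.63). Adgre4 fell from 24.5 ± 1.95 to 4.64 ± 1.98 FPKM and Ace, the angiotensin-converting enzyme, from 4.60 ± 0.672 to 0.412 ± 0.0286.

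**Figure D3:**
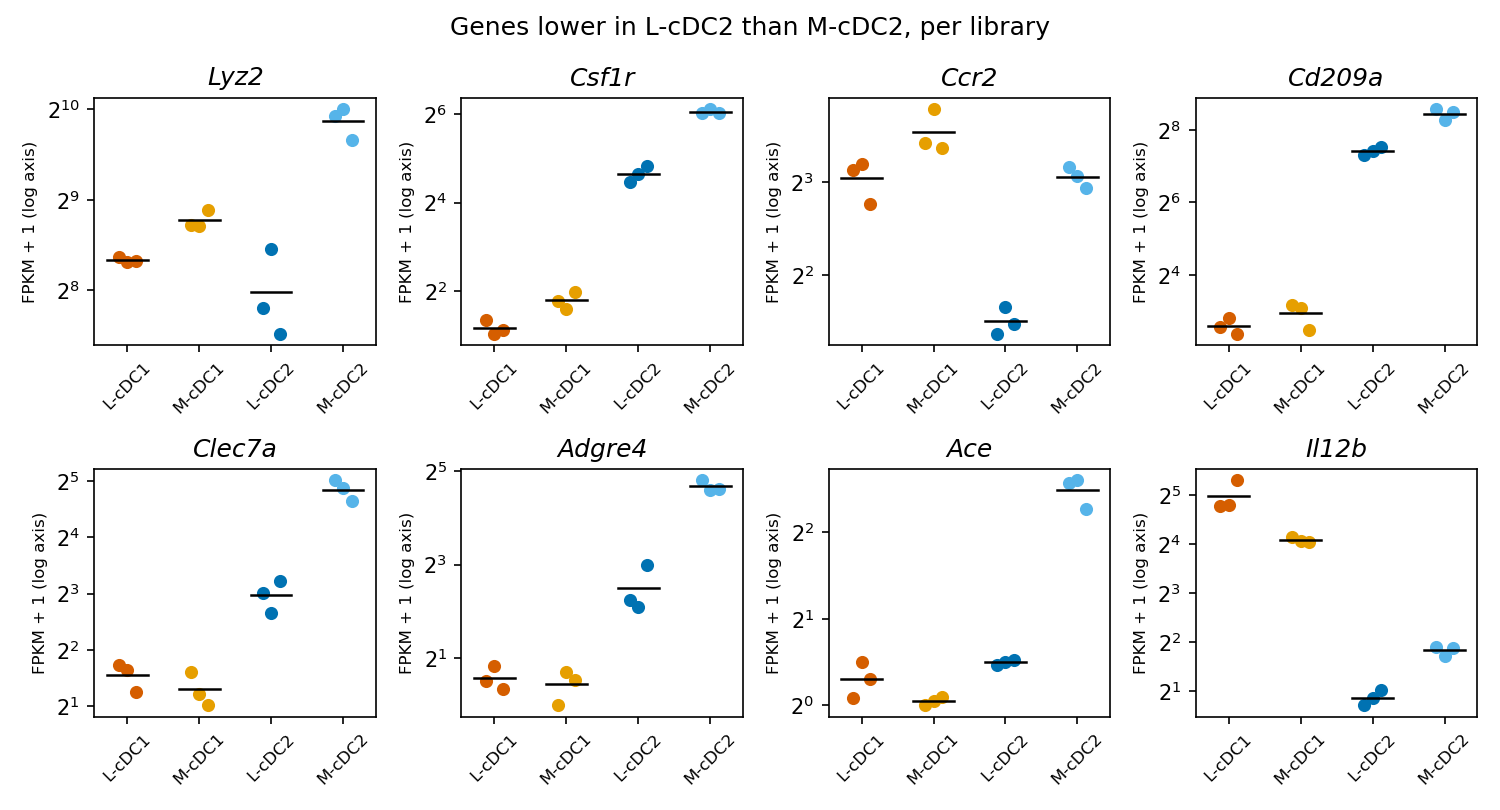
FPKM + 1 on a log axis for 8 genes in each library, with points for libraries and bars for means of 3. Lyz2 has a mean of 252 FPKM in L-cDC2 against 932 in M-cDC2, and Csf1r 24.1 against 65.3.

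Of 21 cytokine genes 5 fell, Ccl9, Ccl6 (-1.40), Il12b (-0.97), Cxcl16 (-0.92) and Il1b (-0.82), or 9 fell and 1 rose adjusted over the list alone (-0.418, adjusted p = 4.4e-07, and 0.00504 with an estimated correlation). Il12b fell from 2.57 ± 0.227 to 0.831 ± 0.199 FPKM. Of 25 innate sensors Tlr12 (1.23), a sensor of profilin, rose and Clec7a and Clec9a (-0.83) fell, or 1 and 3 adjusted over the list alone (-0.132, adjusted p = 0.00516, and 0.0397 with an estimated correlation). Of 15 growth factor receptors Csf1r, Csf2rb2 (-1.06) and Csf3r (-1.49) fell, or 4 fell and 1 rose adjusted over the list alone (-0.197, adjusted p = 0.00295, and 0.0883 with an estimated correlation). Of 20 cDC1 identity genes Clec9a, Naaa (-0.75) and Ifi205 (-0.89) fell, or 7 fell and 1 rose adjusted over the list alone (-0.236, adjusted p = 0.00326, and 0.0716 with an estimated correlation). Il12b and Apol7c (-0.43) fell among 21 DC maturation genes, also over the list alone (adjusted p = 0.0246, and 0.265 with an estimated correlation), and 0 of 15 MHC class II genes passed, or 7 lower and 1 higher adjusted over the list alone (-0.189, adjusted p = 0.00181, and 0.0633 with an estimated correlation). Quantile normalization ended the calls of DC maturation (adjusted p = 0.0886, range 0.021 to 0.265), MHC class II (0.153, range 0.00145 to 0.153), ribosomal proteins (0.178, range 0.0012 to 0.581) and oxidative phosphorylation (0.163, range 0.018 to 0.483).

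No member was called of the cDC2A list (0.17, adjusted p = 0.0376, and 0.215 with an estimated correlation, with 2 higher over the list alone), the cell cycle list (0.218, 0.0286 and 0.483), ribosomal proteins (-0.0739, 0.00344 and 0.581) or oxidative phosphorylation (-0.0619, 0.0256 and 0.483). Ikzf3 (1.36) and 1 other gene rose among 31 DC transcription factors (0.798), Ly6d and Blnk (1.67) among 14 pDC markers (0.154), and Csf3r fell of the pair of neutrophil markers (0.103). Adjusted p was 0.0977 for erythroid, 0.159 for stromal, 0.154 for MHC class I, 0.112 for interferon response, 0.876 for immediate early, 0.742 for checkpoint, 0.204 for glycolysis and 0.0917 for sex-linked genes. In total 227 genes passed, 129 higher (51 of them immunoglobulin or T cell receptor genes) and 98 lower, and 1267 had an unadjusted p under 0.05. The balance depended on the genes and libraries used. It was 64 higher and 78 lower under a filter of 5 FPKM, and 59 and 85 without lymphocyte list genes. Genes of lymphocytes outside those lists, such as Fcmr and Ly6d, stayed in the latter fit. Without L-cDC2 replicate 2 the balance was 76 and 79. The lower genes came to 59 without L-cDC2 replicate 1, 50 without M-cDC2 replicate 2 and 59 without M-cDC2 replicate 3. Without M-cDC2 replicate 2 the count was 138 and without M-cDC2 replicate 3 it was 150, and 13 of 63 named calls ended in 1 or more such fits, all 13 of them without M-cDC2 replicate 2. Among them adjusted p reached 0.223 for Ltb4r1, 0.106 for Cx3cr1, 0.0952 for Ifi205 and 0.064 for Csf3r without that library, 0.213 for Ikzf3, 0.212 for Apol7c, 0.0946 for Vpreb3 and 0.0887 for Blnk without L-cDC2 replicate 2, 0.0977 for Cr2 without L-cDC2 replicate 3, 0.149 for Il1b without M-cDC2 replicate 1 and 0.153 for Tmem176b without M-cDC2 replicate 3. Under every alternative that tested the gene 37 of the 63 calls were kept. Of the others, 19 ended with the compared groups alone, 14 without a filter, 9 with a pseudocount of 0.1, Adgre4 among them (adjusted p = 0.0813, range over the alternatives 0.000116 to 0.0813), and 7 with limma-voom.

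The L minus M differences of cDC1 and cDC2 rest on separate libraries, but their calls share the spread of each gene from 1 fit. The overlaps by chance and the Fisher's exact tests treat the calls as independent and so describe the overlap only. Of the genes higher in L, 22 were shared (0.456 by chance if independent, one-sided Fisher's exact p = 6.01e-33), 9 of them immunoglobulin or T cell receptor genes, and the others included Cd79a, Ly6d, Fcmr, Nkg7 and Jchain. Of the genes lower in L, 3 were shared, Fcer1g, Krt80 and Gm35853 (0.0394 by chance, one-sided Fisher's exact p = 4.69e-06). Il12b was the gene that passed in both with opposite signs, at 0.87 in cDC1 and -0.97 in cDC2. Tests of the difference itself, the interaction, passed for 37 genes, 24 more toward cDC1 and 13 more toward cDC2, and 1061 had an unadjusted p under 0.05. Of the 24, 10 were called lower in L-cDC2 and had means under 1 FPKM in both cDC1 groups, where such a fall could not be seen on the log2(FPKM + 1) scale, so for these the test does not show a response that differs between the subsets. Psap, a precursor of lysosomal activator proteins, was at 4172 ± 98.3 and 4073 ± 458 FPKM in L-cDC1 and M-cDC1 but at 322 ± 54.4 and 868 ± 91.2 in L-cDC2 and M-cDC2 (interaction 1.48, SE 0.175, limma adjusted p = 0.00581). Il12b (1.83) had the same adjusted p, 0.00581, and Clec7a (2.14), at 1.93 and 1.46 FPKM in L-cDC1 and M-cDC1, one of 0.00851. From 1.46 FPKM, a fall as large as the -1.88 of Clec7a in cDC2 could not be seen in cDC1 on this scale either. Ace (2.23), Cd300lb (1.93) and Clec4a3 (1.88) also passed but were among the 10 genes near 0 in cDC1. The interaction count moved to 24 without L-cDC1 replicate 3, 14 and 21 without M-cDC1 replicates 2 and 3, and 23, 9 and 18 without M-cDC2 replicates 1, 2 and 3. It was 9 with limma-voom, which ended the calls of Il12b and Clec7a. Of 100 regroupings of the samples, the real one among them, 7 gave at least 37 genes. Each subset was regrouped apart, so a regrouping can keep the real L and M groups of 1 subset and carry its difference. The share therefore does not measure how often chance gives such a count, and chance is not excluded.

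**Figure D4:**
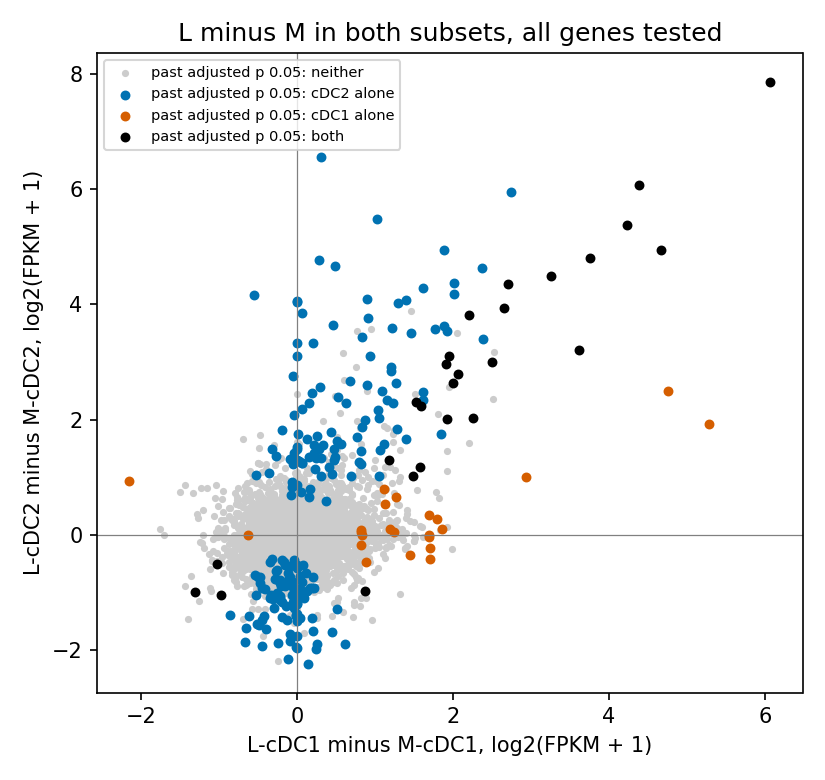
Log2 difference L minus M of each tested gene in cDC1 on the horizontal axis and in cDC2 on the vertical axis, with colours for genes called in neither contrast, in cDC2 alone, in cDC1 alone or in both. The 22 genes called higher in both lie at the upper right, and Il12b lies at 0.87 and -0.97.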

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

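The tests on monocytes, on cDC2B cells, on gene length and GC content and on expression by the L-cDCs themselves were chosen only after the result was seen, as were limma-voom, the length and GC correction and the fit without lymphocyte list genes. By the limma interaction test, which takes the L minus M difference in cDC1 minus that in cDC2, 16 named genes passed. For Ace, Adgre4, Ccl9, Cd300lb and Clec4a3, 5 of the 16, both cDC1 groups had means under 1 FPKM, so that a fall in cDC1 could not be seen and the value largely restates the cDC2 difference (1.93 against -1.94 for Cd300lb). Clec7a was little above 1 FPKM in both cDC1 groups, where a fall as large as its -1.88 in cDC2 could not be seen either. Values above 0 were found for Adgre4 (2.37, SE 0.357, adjusted p = 0.0137), Ace (2.23), Clec7a (2.14), Spib (2.12), Cd300lb (1.93), Clec4a3 (1.88), Il12b (1.83), Ccl9 (1.75), Wfdc17 (1.75), Lyz2 (1.49), Psap (1.48) and Tmem176a (1.1). Values below 0 were found for Gzma (-3.20), the segment Ighj1 (-3.08), Fcrla (-2.13) and Tlr12 (-1.28). Spib differed by 1.70 in cDC1 and -0.41 in cDC2, Tlr12 by -0.046 and 1.23, and Ighj1, named after its values were seen, rests in cDC1 on 0 reads in each L library and 7, 1 and 6 in M libraries. The interaction median was 0.409 for the cDC2 identity list (camera adjusted p = 0.000118, and 0.0277 with an estimated correlation), of which 8 of 20 members were likewise under 1 FPKM in both cDC1 groups (median of the others 0.327), 0.524 for cytokines and chemokines (2.54e-06 and 0.0151) and -1.2 for T and NK cell markers (6.38e-11 and 0.05, just under the threshold before rounding).

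Of the 16 calls, Ace was the one kept under every alternative that tested it (adjusted p 0.00171 to 0.0486), with the limit above. With a mean of 4.60 FPKM in M-cDC2 and less in the other groups, Ace was not tested under the filter of 5 FPKM. Without each library 6 calls were kept. Leaving out M-cDC2 replicates 1, 2 and 3 ended 6, 10 and 4 calls, M-cDC1 replicates 4, 6 and 4, L-cDC2 replicates 5, 3 and 3 and L-cDC1 replicates 3, 5 and 5. Without M-cDC2 replicate 2 the adjusted p was 0.0629 for Adgre4 (range over the alternatives 0.00775 to 0.279), Ccl9 (0.00368 to 0.87), Fcrla (0.0048 to 0.0996), Ighj1 (3.59e-06 to 0.206), Wfdc17 (0.00698 to 0.295) and Tlr12 (0.0157 to 0.114). There it was 0.0875 for Lyz2 (0.0017 to 0.176) and Tmem176a (0.0219 to 0.162), 0.157 for Spib (0.00385 to 0.231) and 0.115 for Gzma (0.0242 to 0.549). Limma-voom ended 13 of the calls, with Cd300lb at 0.846 (0.00321 to 0.846), Clec4a3 at 0.454 (0.00442 to 0.454) and Clec7a and Il12b at 0.0828 (from 0.00442 and 0.00422 to 0.0828), and the fit without a filter ended 10, with Psap at 0.0589 (0.000933 to 0.0589). Of 100 splits of the samples drawn, 7 gave at least the 37 interaction genes of the real one, with 78 in the highest other. Because a split can keep the real L and M groups of 1 subset, it can carry a real difference. The splits thus cannot decide whether chance gives that count, and chance is not excluded for it.

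For 3 against 3 libraries the splits are too few for a share under 0.05. In L minus M the real split gave 49 genes in cDC1 against 3 in the highest other, and 227 in cDC2 against 1. For cDC1 minus cDC2 the real split gave 4736 genes in M against 0, and 4913 in L against 3. In each of these 4 contrasts 1 of 10 splits, the real one, gave as many. Every other split mixes libraries of both groups, so genes that differ between the groups gain spread within it. The low counts of the other splits therefore do not measure how many calls chance gives.

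B, T and NK cell transcripts were higher in the L libraries, with 19 of 27 tested markers called in cDC2 but 7 of 16 B cell and 3 of 11 T and NK cell markers in cDC1, where neither list passed with an estimated correlation (adjusted p = 0.0944 for each). A source in L-cDC2 replicate 2 alone is argued against, since 17 of the 19 markers called in cDC2 still passed without it. Lymphocytes or their RNA in the L libraries are a candidate explanation, because even the lowest L library held 25 kappa V genes with at least 3 reads against a median of 1.5 in M libraries, and a mixture of B cells brings many V genes at once. Expression by the L-cDCs themselves cannot be told apart from this for these markers, since either would give the L minus M difference above 0 that 27 of 27 had in both subsets, called or not, and 11 reached a mean of 1 FPKM in an M group too. The lymphoid progenitor genes Ly6d, Tcf7 and Vpreb3 are not among the 27 markers, and their source was not tested. The labels' protocols used here describe no gate that would remove lymphocytes, and a difference between L and M cells stays open as untested.

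Some genes of monocytes and of the cDC2B class were lower in L-cDC2. Of 18 monocyte and macrophage markers 5 were called lower, 1, Apoe, was called higher and 12 did not pass. Classical monocytes in the M-cDC2 libraries are argued against, since 5 of their abundant genes summed to 1.29 FPKM there (Ly6c2 0.945, Fcgr1 0.244, F13a1 0.0618, C5ar1 0.0351 and Vcan 0), 0.189% of the Lyz2 difference of 679.5 FPKM. Non-classical monocytes in M-cDC2 may contribute, since of 12 of their genes Ace, Ear2, Cx3cr1 and Adgre4 were called lower in L-cDC2, but the 8 with a difference below 0 include 4 that did not pass, and 8 of the 12 also reached 1 FPKM in M-cDC1. Fewer cDC2B cells among L-cDC2 may contribute as well, with 6 of 9 class members called lower and 1 called higher (differences below 0 in 7, called or not), and 3 of the 9 stand in the monocyte list too. These sources cannot be told apart because each explains part of its list only, and a difference in expression between L and M cells stays open as untested.

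The 79 ribosomal protein genes had a median L minus M difference of -0.342 in cDC1, with 0 members called and the list past the test with the preset correlation (adjusted p = 2.1e-27) but not with an estimated correlation (adjusted p = 0.169), so that a shift of the list as a whole between libraries is not excluded. Their median length was 1781 bp against 3682 bp over all genes, and across 12434 genes, which are not independent replicates, the L minus M difference had a Spearman correlation of 0.18 with length. A bias by length or GC content as the whole source of the negative median is argued against, since it was still -0.305 after the correction. A difference in RNA quality and a difference between L and M cells stay open as untested.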

How the results depend on the processing

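Limma-voom, the length and GC correction and the fit without lymphocyte list genes were chosen only after the result was seen. For L minus M in cDC1 the count of 49 genes moved to 80 with a pseudocount of 0.1, 14 without a filter, 82 with a filter of 5 FPKM, 17 with the compared groups alone and 16 without lymphocyte list genes, and ran from 24 (without M-cDC1 replicate 2) to 102 (without M-cDC1 replicate 1). In cDC2 the count of 227 moved to 142 with a filter of 5 FPKM, 137 with the compared groups alone and 144 without lymphocyte list genes, and ran from 138 (without M-cDC2 replicate 2) to 190 (without L-cDC2 replicate 3). The interaction count of 37 moved to 21 with a pseudocount of 0.1 and 9 with limma-voom, and ran from 9 (without M-cDC2 replicate 2) to 38 (without M-cDC1 replicate 1). The counts of 4736 in M and 4913 in L stayed within 1.5 times under each alternative, at 3847 to 4176 and 4125 to 4525 with a library left out. The genes called changed more with the scaling. Of these calls 3842 in M and 3974 in L were also made after median-of-ratios scaling, and 3473 and 3680 after quantile normalization. The filters and the fit without lymphocyte list genes change which genes are tested and the fit to the compared groups uses fewer samples, while for the others the cause was not tested. With an estimated correlation 0 of 14 lists still passed for L minus M in cDC1, 8 of 17 in cDC2, 4 of 16 for cDC1 minus cDC2 in M, 6 of 14 in L and 3 of 16 for the interaction. For the 14 lists in cDC1, fry gave adjusted p = 0.00672 for B cell and 0.00817 for T and NK cell, lymphoid progenitor and DC maturation genes. It gave 0.0173 for cDC2A and oxidative phosphorylation, 0.0321 for DC transcription factors and 0.037 for ribosomal proteins. The cDC2B and erythroid (0.0614), plasma cell (0.0788), immediate early (0.101), monocyte (0.118) and cell cycle lists (0.445) did not pass it. Signs reversed as follows, and the cause was not tested. In L minus M cDC1, Flt3 became -0.012 with median-of-ratios scaling, -0.011 with limma-voom, -0.043 with the length and GC correction and -0.023 to 0.081 with a library left out, Irf8 became -0.0035 with that correction, Batf3 ran from -0.19 to 0.014 and Il7r from -0.081 to 0.12. Irf8 in cDC2 ran from -0.24 to 0.20, Zbtb46 in L became 0.0089 with median-of-ratios scaling and 0.011 with limma-voom, and in M quantile normalization gave -0.37 for H2-Ab1 and -0.33 for H2-Aa. Over the named genes and all alternatives, direction and side of the threshold were kept in 447 comparisons for L minus M in cDC1, 1038 in cDC2, 2248 and 2274 for cDC1 minus cDC2 in M and L and 245 for the interaction, and the call was lost in 105, 118, 61, 62 and 100. Genes named whether or not they passed, such as Flt3, count as kept where they stayed uncalled. An alternative that did not test a gene was not counted for it. Deviations of same-numbered libraries correlated from -0.00171 to 0.156. Libraries with different numbers were not compared, so these values cannot tell whether the replicate numbers pair the samples. With the number as a replicate block 45, 233, 4754 and 4952 genes passed in these contrasts and 25 for the interaction, and it ended 3 named calls in each L minus M contrast and the interaction and 0 in cDC1 minus cDC2. It also ended the list calls of immediate early genes in M (adjusted p = 0.0669, range over the alternatives 0.00144 to 0.447) and DC transcription factors in the interaction (0.0609, range 0.0266 to 0.298). The count tests and TMM scaling foreseen only for a deposited table of raw counts were not run, and limma-voom on the recovered reads was the count-based alternative used. On a gene of 1 kb, 3 reads were worth 0.122 to 0.189 FPKM, and a difference in Rag1, with at most 1 read in a library, was not detectable at this depth.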

Other observations

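The enrichment tests on gene ontology terms were chosen only after the result was seen, and used the annotation column of the deposited table, which covers 82.4% of the tested genes, with immunoglobulin and T cell receptor genes left out (2441 terms, one-sided hypergeometric test, Benjamini-Hochberg adjusted). Genes without a term stayed in the background, so the counts by chance are too low. The test also treats genes as independent, so its p-values describe the overlap only. Among genes lower in L-cDC2, neutrophil chemotaxis held 7 of 33 genes (0.262 by chance, adjusted p = 4.71e-06), which were Ccl6, Ccl9, Csf3r, Fcer1g, Il1b, Il1rn and Lgals3. Response to interferon-gamma held 5 of 19 (0.151 by chance, adjusted p = 0.000185), Cxcl16, Ifitm2, Ifitm3, Mefv and Slc11a1. Lysosome held 11 of 292 (2.32 by chance, adjusted p = 0.00352), among them Psap, Npc2, Scarb2 and Slc11a1. Further terms were inflammatory response 9 of 159 (1.26, adjusted p = 0.00137) and extracellular space 21 of 373 (2.96, adjusted p = 2.58e-09). Among genes higher in L-cDC2, B cell activation held 6 of 26 (0.164 by chance, adjusted p = 8.88e-06) and external side of plasma membrane 16 of 196 (1.24, adjusted p = 1.57e-10).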
